A study of Mus musculus with 18 samples.

How the data were processed

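Gene expression was measured in astrocytes isolated from the primary motor cortex (M1) of C57BL/6 mice, in 18 libraries, with 6 each from untrained (naive), novice and expert mice. Per the labels' protocols, total RNA was recovered by proteinase K digestion of the cells and cleaned on a silica column. Indexed stranded total RNA libraries were made with the SMARTer kit and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were processed with TopHat and Cufflinks against mouse build mm9. Versions, options and the annotation are not given in the sources used here.

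The deposited table holds 1 value per gene and library in FPKM (fragments per kilobase of transcript, scaled to the mapped total of the library), although the authors' title for it speaks of normalized counts. The unit was checked on the values. For 133 olfactory receptor genes with a single annotated transcript, 64.8% to 76.9% of the low values multiplied by transcript length lay within 0.1 of a whole multiple of a step in 17 libraries. The step was chosen in each library for the closest agreement, and a step not chosen that way would give about 20%. Expert 3, at 23.5%, showed no such step. Any further scaling that the authors applied between libraries is not given in the sources used here. The table had 23951 entries. Of these, 27 carried names that a spreadsheet had turned into dates and were left out, and 23924 genes were read. Named genes under 0.001 FPKM in a library are described as listed at 0.

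Read totals are not part of the deposited values, so depth was described by what the values show. The FPKM value of 1 fragment on a transcript of 1 kb was taken from that step and ranged from 0.594 to 1.89 among the libraries other than expert 3, for which it is unknown. The number of genes at exactly 0 ranged from 2257 to 5430.

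Genes with at least 1 FPKM in at least 6 of the 18 libraries were tested, which left 21745 genes. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 1 mean per group and all 18 libraries in a single fit. The 3 comparisons were novice against naive, expert against naive and expert against novice, and a moderated F test covered any difference among the 3 groups. Tests were two-sided, and p-values were adjusted over all tested genes by the method of Benjamini and Hochberg, with a threshold of 0.05. The median log2 fold change of all genes was 0.07 for novice against naive, -0.05 for expert against naive and -0.14 for expert against novice. It differed with abundance, at -0.07, 0.01 and 0.11 with a filter of 5 FPKM and -0.19, -0.01 and 0.22 with one of 20 FPKM, so changes are to be read relative to genes of like abundance. Trimmed mean of M values factors brought the median of all genes to 0.02, 0.02 and -0.03. The labels give an age and a sex for each library. They do not say in so many words that each library came from a separate animal, so the p-values measure the spread between libraries.

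Lists of genes, 33 in number and covering astrocyte functions, stress and activity responses and markers of other brain cell types, were fixed before the data were examined, as were the comparisons, the filter, the tests and most of the other settings tried. The mitochondrially encoded genes could not be tested, because 0 of 13 are in the table, and 32 lists were tested. Some lists share members, so their calls are not independent. Aqp4, Slc4a4, Mlc1 and Atp1b2 are in the lists of astrocyte identity and of potassium, water and ion homeostasis. Slc2a1 is in that of glycolysis, glycogen and lactate and among the endothelial markers. Lists were compared with the other genes by camera with the correlation between genes preset at 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the data was run beside it. So was the rotation test fry, which asks whether a list changed at all, not whether it differs from the other genes. A count "adjusted over the list alone" corrects the gene p-values for the members of that list only. It is not corrected for the 32 lists, so that members of some lists can pass by chance. In the 3 comparisons 2, 2 and 7 members passed in this way. In single-value comparisons between groups, all splits of the libraries were enumerated (exact permutation test, two-sided).

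Genes named in the text follow a rule that was fixed at the same time. It takes genes past the threshold or, where none passes, the 5 with the smallest p in each direction and comparison, up to 4 members with the smallest p from each list, and always Slc1a2, Slc1a3, Gfap, Aqp4, Aldh1l1 and Gja1. Predicted loci were not named. Values are the mean ± SD of 6 libraries in FPKM, and fold changes are log2 values with the standard error of the fit.

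After the values were seen, a background was measured in each library as the mean FPKM over 1319 autosomal genes of families that are silent in most brain cells (olfactory, vomeronasal and trace amine receptors, defensins and keratin-associated proteins), after the share of 0.1 with the highest means had been left out. Its log2 value served as a covariate in added fits, and other added fits subtracted it. Chromosome membership came from RefSeq on GRCm38, a later assembly than mm9, and no coordinates were used. The 18 libraries were divided at 1.8 FPKM into a higher and a lower background class. These classes were defined from the data and are not groups of the study.

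The procedure was tested on simulated data made from the shuffled residuals of all 18 libraries, in 5 runs with 200 changed novice genes each. It called 20% of genes changed by 1 on the log2 scale, 76.7% of those changed by 2 and 95.2% of those changed by 3, with 28 false calls over all runs. The 22 astrocyte identity genes raised by 1 in expert were called as a list in 5 of 5 runs by camera with the preset correlation. False calls of lists were not counted in these runs. When the real libraries were regrouped into 100 splits per comparison, the same test called lists in 90, 97 and 96 of the splits other than the real one. The runs therefore do not show how often lists are called without a change.

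The other settings fixed at the same time were other pseudocounts, filters and scalings, the replicate number as a block, sex, age or neuron marker level as covariates, library weights, other variance priors, fits of 2 groups only and leaving out each library. A count-based test on recovered fragment numbers was also intended. It was not run, because too few of the low values lay near whole multiples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.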

Results

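The series asks how learning a motor skill affects astrocytes of the motor cortex. Water-restricted mice learned to push a lever after a cue for a water reward. Astrocytes from M1 were profiled after 3 days of training (novice), after full training (expert) and without training (naive). There were 18 libraries, 6 per group, each group with 2 labelled female and 4 labelled male, from mice of 12 to 21 weeks in naive, 11 to 13 in novice and 13 to 15 in expert. The deposited values are in FPKM, and 21745 genes were tested.

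The libraries were rich in astrocyte transcripts. Slc1a2, the main glutamate transporter of astrocytes, stood at 1397 ± 712 FPKM (SD, n = 6) in naive, 883 ± 442 in novice and 1565 ± 752 in expert. Slc1a3, the other astrocyte glutamate transporter, stood at 477 ± 233, 308 ± 144 and 535 ± 268 FPKM, and the gap junction gene Gja1 at 217 ± 91.1, 153 ± 55.7 and 274 ± 148 FPKM. Across the 22 astrocyte identity genes the mean log2(FPKM + 1) was 7.24 in naive, 6.71 in novice and 7.43 in expert. In the naive libraries the means of other cell types' markers were 4.99 for endothelial cells, 4.44 for neurons, 3.06 for oligodendrocytes, 3.03 for pericytes, smooth muscle and fibroblasts, 2.40 for microglia and macrophages and 2.03 for blood cells. A single transcript, Bc1, a noncoding RNA of neurons, held 6.01% to 59.6% of the summed FPKM of a library. As FPKM is scaled to transcript length, this is not its share of the fragments. It was 18.4% to 59.6% in the libraries of the lower background class and 6.01% to 19.2% in those of the higher class. The value of 1 fragment on 1 kb of transcript, an inverse measure of depth, was 0.808 to 1.89 FPKM in naive, 0.716 to 1.68 in novice and 0.594 to 1.72 in expert without expert 3, for which it could not be read from the values. Between 2257 and 5430 genes were at exactly 0, the most in expert 3.

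Libraries differed widely in signal over genes that are silent in most brain cells. The mean over 1319 such autosomal genes was 1.75 ± 1.11 FPKM in naive, 2.19 ± 0.897 in novice and 1.38 ± 1.02 in expert. Exact permutation tests over 924 splits gave p = 0.50 for novice against naive, 0.56 for expert against naive and 0.17 for expert against novice. The lowest library was expert 3, at 0.109 FPKM. The other libraries lay at 0.681 to 1.52 FPKM or at 2.18 to 3.16 FPKM, and the latter 8 comprised 2 naive, 4 novice and 2 expert libraries. The first principal component held 38.6% of the variance, with scores of -95.2 to -6.25 in the 10 libraries of lower background and 28.6 to 70.1 in the 8 of higher background. Astrocyte identity genes were lower where this background was higher, with Pearson's r at -0.96 over all 18 libraries. Within the 10 lower libraries, Pearson's r of their mean against the log2 background was -0.87 (permutation p = 0.0023) and Spearman's rho was -0.82 (permutation p = 0.0053). Without expert 3 and expert 1, which lay farthest from the median, r was -0.66. Within the 8 higher libraries r was -0.68 (exact permutation p = 0.066) and rho was -0.62 (exact permutation p = 0.11), and r was -0.44 without expert 5 and novice 6. Adjusted over the 12 relations computed, p was 0.014 and 0.13. Of other cell types, only markers of neurons, endothelial cells and microglia were examined, and no Pearson relation passed when adjusted. Signs went both ways, but the positive values shrank or turned negative without the 2 libraries farthest from the median. For neuron markers r was -0.56 over all 18 libraries (permutation p = 0.016, adjusted 0.065) and rho was -0.70 (permutation p = 0.0018, not adjusted). Without expert 3 and naive 5, r was -0.87. Within the lower libraries r was 0.53, and 0.08 without expert 3 and expert 1. Within the higher ones r was -0.70 (exact permutation p = 0.053, adjusted 0.13), and -0.71 without expert 5 and novice 6. For endothelial markers r was -0.27, -0.54 and -0.76 (exact permutation p = 0.034 in the higher ones, adjusted 0.10), and for microglia and macrophage markers 0.22, 0.67 and -0.08. Without the same pairs of libraries r was 0.00, -0.39 and -0.50 for endothelial markers. It was -0.45, 0.10 and -0.11 for microglia and macrophage markers. Comparisons of gene lists are therefore given with and without this background as a covariate.

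**Figure D1:**
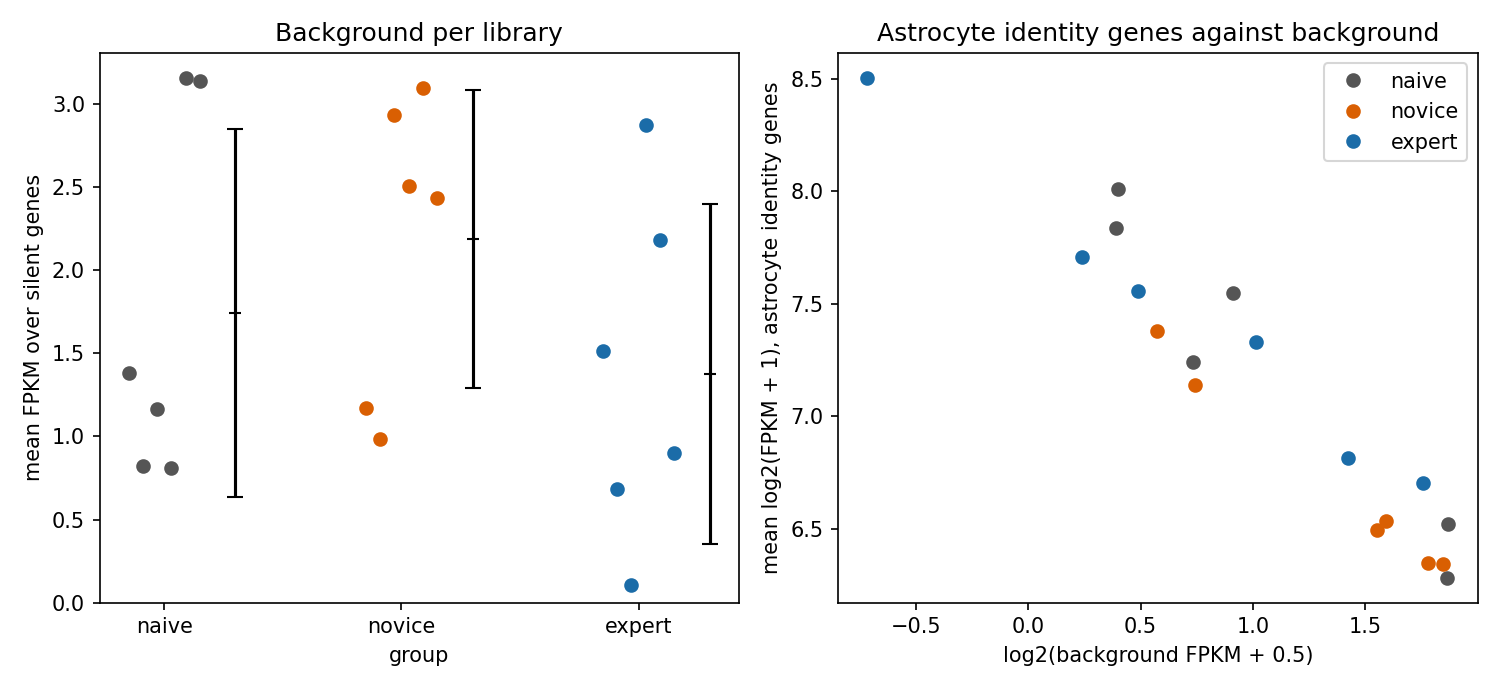
Background per library, as mean FPKM over 1319 silent genes (left, points are libraries, bars are the mean and SD of 6), and the mean log2(FPKM + 1) of 22 astrocyte identity genes against log2(background FPKM + 0.5) (right). The background runs from 0.109 FPKM in expert 3 to 3.16 FPKM, in all 3 groups, and the astrocyte mean lies lower at higher background.

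Transcripts of the sex chromosomes went against the labelled sex in 2 libraries. Novice 1, labelled female, had 1.60 FPKM of Xist, the transcript of the inactive X, and 12.6 FPKM of the Y-linked Ddx3y. Novice 3, labelled male, had 18 FPKM of Xist and 3.29 FPKM of Ddx3y. With the labels as given, limma called 0 genes for sex, with 290 at an unadjusted p under 0.05. Without both libraries it called 5, of which Xist was higher in female by 3.17 (SE 0.30) on the log2 scale. Both had been left out for their Xist and Ddx3y, so these calls are not independent evidence. Eif2s3y, Ddx3y, Kdm5d and Uty, all on the Y chromosome, were lower by 3.05, 2.12, 1.89 and 1.59 on the log2 scale.

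Novice against naive asks what the start of training does. Astrocyte genes stood lower in novice libraries. Gfap, the intermediate filament of astrocytes, was 10.6 ± 2.07 FPKM in novice and 19.4 ± 9.70 in naive (n = 6 each), a log2 fold change of -0.71 (SE 0.29). The water channel Aqp4 stood at 39.8 ± 11.6 against 61.0 ± 24.0 FPKM (-0.55, SE 0.32). The log2 fold changes of Slc1a2, Slc1a3, Gja1 and Aldh1l1, a folate enzyme used as an astrocyte marker, were -0.61, -0.58, -0.46 and -0.31. Sqle and Fdft1, enzymes of cholesterol synthesis, stood at -0.93 (SE 0.29) and -0.70 (SE 0.30). None of these passed the threshold (adjusted p = 0.89 for each).

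**Figure D2:**
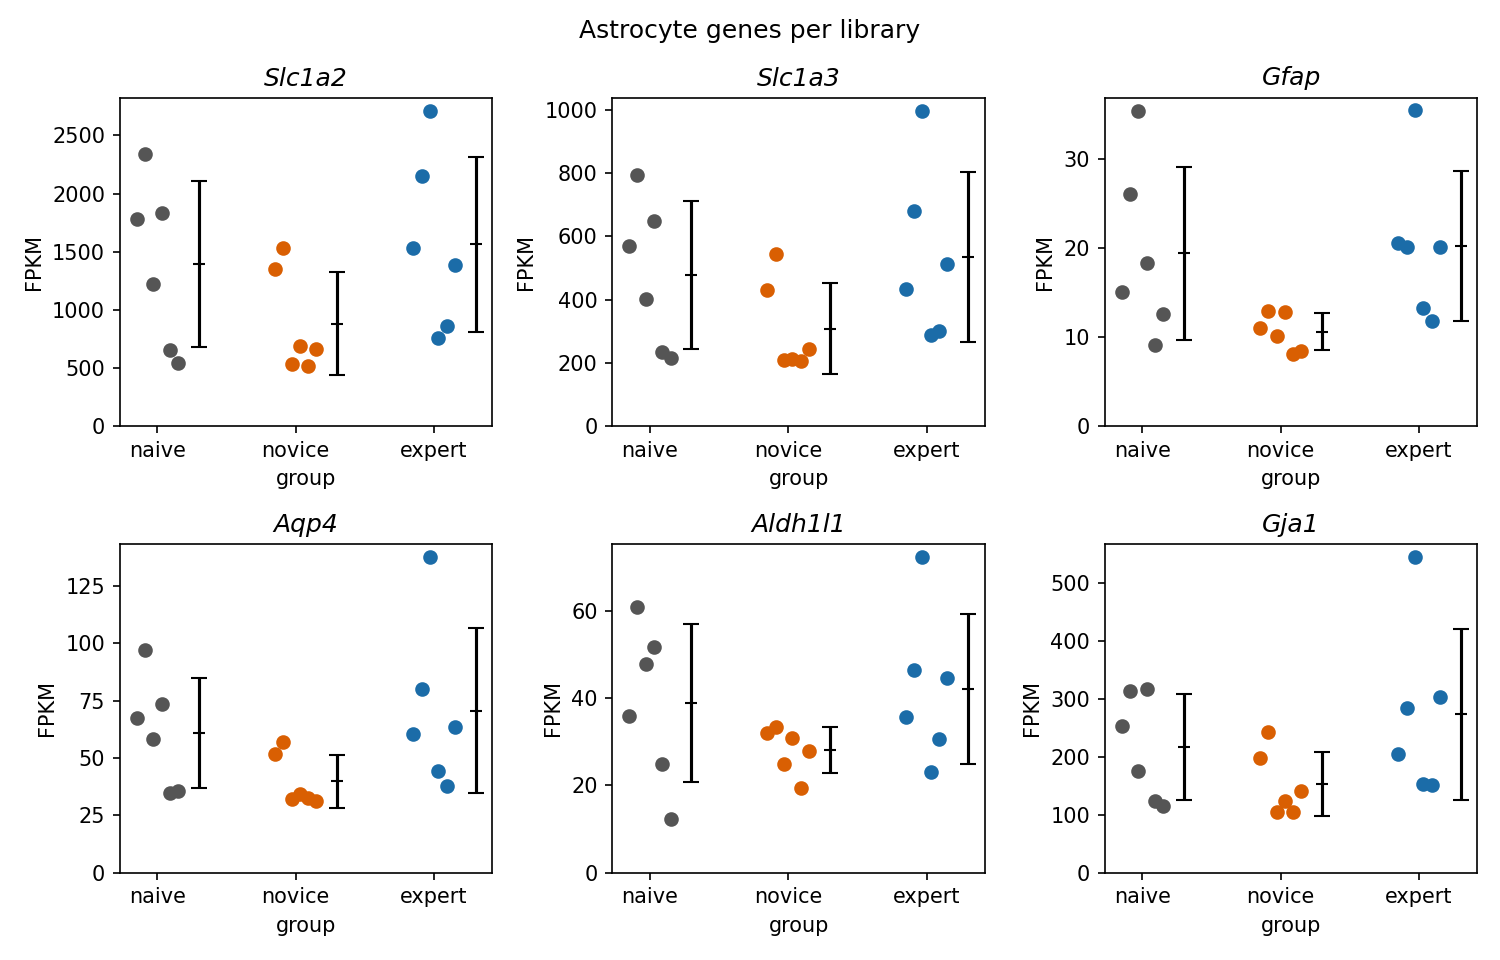
FPKM of Slc1a2, Slc1a3, Gfap, Aqp4, Aldh1l1 and Gja1 in each library (points) with the mean and SD of 6 libraries per group (bars). The mean of each gene is lowest in novice, as for Gfap at 10.6 FPKM against 19.4 in naive and 20.2 in expert, and the groups overlap.

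The genes with the smallest p in the same comparison included, on the lower side, Mrps16, a protein of the mitochondrial ribosome, at 6.91 ± 3.10 FPKM in novice and 23.2 ± 12.0 in naive (-1.57, SE 0.33). The RNA-binding protein Raly stood at 9.36 ± 2.11 against 18.8 ± 4.34 FPKM (-0.93, SE 0.23), and Leprel4, Npepl1 and the meiotic gene Sycp3 at -0.88, -0.98 and -1.38. The highest novice value of Leprel4 was 3.54 FPKM and the lowest naive value 3.62 FPKM. On the higher side, Dyx1c1, a dynein assembly factor of cilia, stood at 4.65 ± 1.14 FPKM in novice and 2.13 ± 0.323 in naive (0.83, SE 0.19), and no novice library lay below 2.79 FPKM. Ghrl, the ghrelin gene, ranged from 5.82 to 39.6 FPKM in novice and was listed at 0 in 2 of 6 naive libraries, with a naive maximum of 8.48 FPKM. Sprr2f and Fam229a were each listed at 0 in 5 of 6 naive libraries, with novice medians of 3.07 and 4.84 FPKM. Ascl5 was listed at 0 in all 6 naive libraries and in 1 of 6 novice libraries, with a novice median of 3.15 FPKM. The novice medians of Sprr2f, Fam229a and Ascl5 were not far above the novice background over silent genes, at 0.986 to 3.10 FPKM. The value of 1 fragment on 1 kb was 0.716 to 1.68 FPKM in novice. These 10 genes did not pass (adjusted p = 0.89 for each). With limma, 0 of 21745 genes were called, and 1000 had an unadjusted p under 0.05, of which 592 were higher and 408 lower, against 1087.25 expected by chance. With 1 library left out, this count ran from 650 (without naive 2) to 1779 (without naive 5).

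As groups, several lists of astrocyte function lay below the other genes in novice by camera with a preset correlation, and none was called with an estimated correlation (smallest adjusted p = 0.31). Calcium and G protein coupled receptor signalling was not called in either way (median -0.06, 20 of 32 lower, adjusted p = 0.073), but the preset correlation called it without naive 5, naive 6, novice 1 or novice 2, where the median log2 fold change of calcium and G protein coupled receptor signalling, novice against naive, was -0.14, -0.18, -0.13 and -0.14. The median over all genes past a filter of 20 FPKM was -0.19 in this comparison. The astrocyte identity list had 22 of 22 members lower, with a median log2 fold change of -0.56, and the list of potassium, water and ion homeostasis had 17 of 17 lower (median -0.36). Slc7a10, a serine transporter of astrocytes, stood at -0.63 and Sox9, a transcription factor of the lineage, at -0.60. Transporter genes followed, with 12 of 15 members of the glutamate list lower (median -0.38) and 11 of 14 of the GABA list (median -0.45), among them the GABA transporter Slc6a11 at -0.72. Lower too were 24 of 29 genes of glycolysis, glycogen and lactate (median -0.34), with the phosphofructokinases Pfkm at -0.86 and Pfkp at -0.62, 21 of 24 of cholesterol synthesis (median -0.34), 21 of 24 of fatty acid metabolism (median -0.38) and 34 of 39 nuclear genes of oxidative phosphorylation (median -0.34). Replication dependent histones had 10 of 11 lower (median -0.66), led by the linker histone Hist1h1e at -0.98 (SE 0.30). Hist1h1e was the only histone to pass when adjusted over the list alone, and Dynlrb2, a dynein light chain on the ependymal list, the other gene of any list to do so. Dynlrb2 was listed at 0 in 4 of 6 naive libraries and had a novice median of 5.60 FPKM. Single libraries moved some of these medians. The median log2 fold change of glutamate uptake and metabolism, novice against naive, was -0.19 without novice 3 and -0.57 without naive 6, the median log2 fold change of GABA handling and receptors, novice against naive, -0.29 without naive 2, the median log2 fold change of potassium, water and ion homeostasis, novice against naive, -0.55 without naive 6, and the median log2 fold change of oxidative phosphorylation, nuclear genes, novice against naive, -0.17, -0.21, -0.56 and -0.19 without naive 2, naive 4, naive 6 and novice 6.

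Camera with the preset correlation called 16 of 32 lists for novice against naive, all lower, the above among them. It also called ribosomal proteins (63 of 70 lower, median -0.19), heat shock and chaperones (-0.21), endoplasmic reticulum stress (-0.16) and circadian clock genes (-0.25). The others it called were secreted synaptogenic factors (-0.29), synaptic adhesion (-0.27) and phagocytosis and complement (-0.25). With an estimated correlation it called 0, at adjusted p = 0.41 for astrocyte identity, for potassium, water and ion homeostasis, for GABA, for glutamate, for glycolysis, for cholesterol and for fatty acids, 0.61 for oxidative phosphorylation and 0.31 for the histones. Fry also called 0 (smallest adjusted p = 0.49), and 0 in either direction (0.71). With the background covariate, 11 of the 16 calls were kept, with medians of -0.26 for astrocyte identity, -0.18 for potassium, water and ion homeostasis, -0.19 for cholesterol synthesis and -0.50 for the histones. With the covariate and an estimated correlation 0 were called (adjusted p = 0.16 for astrocyte identity, smallest 0.14). With the covariate and the preset correlation, the call of oxidative phosphorylation was not kept (median -0.06, adjusted p = 0.32). Nor were those of ribosomal proteins (0.02, 0.83), heat shock (-0.04, 0.42), endoplasmic reticulum stress (-0.05, 0.20) and secreted synaptogenic factors (-0.20, 0.083). Markers of endothelial cells had a median of -0.02, which turned to 0.12 under quantile normalization, and the list was not called (adjusted p = 0.37), except without novice 6, where the median log2 fold change of endothelial markers, novice against naive, was -0.13.

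Expert against naive asks what full training leaves behind. Genes of blood vessels stood higher in expert libraries. They had been listed as markers of cells that the isolation of astrocytes could carry along. A different share of vessel cells in the libraries therefore cannot be told apart from an effect of training. All 15 endothelial markers had higher means, with a median log2 fold change of 0.55. Expert 3 and expert 6 stood apart, with means of 6.12 and 6.27 in log2(FPKM + 1) over these markers, while the other expert libraries lay at 4.80 to 5.46 and the naive ones at 4.76 to 5.23. Among them, the VEGF receptor Flt1 was 87.1 ± 33.3 FPKM in expert and 53.0 ± 9.87 in naive (0.64, SE 0.25, n = 6 each), the tight junction gene Cldn5 56.5 ± 26.0 against 32.2 ± 5.90 FPKM (0.70, SE 0.28), the cadherin Cdh5 30.5 ± 10.1 against 18.2 ± 3.0 FPKM (0.67) and the angiopoietin receptor Tek 22.5 ± 7.65 against 13.4 ± 2.11 FPKM (0.65). The pericyte genes Rgs5 and Pdgfrb stood at 0.64 and 0.48. Of these genes, 0 passed over all genes (adjusted p = 1.0 for each).

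Genes that respond quickly to stimulation, and also to the dissociation of cells, stood higher in expert as well. These sources were not told apart. Of the 37 immediate early genes, 26 had higher means (median 0.32). Sik1, a salt-inducible kinase, was 11.5 ± 3.34 FPKM in expert and 5.81 ± 1.70 in naive (0.87, SE 0.23), and it was the only member of its list to pass limma's test when adjusted over the list alone (adjusted p = 0.041). That adjustment does not count the other lists. The phosphatase Dusp1 stood at 0.99 (SE 0.31), the transcription factor Klf6 at 0.70 and Btg2 at 0.65. Among glucocorticoid responsive genes, 16 of 24 had higher means (median 0.13), and the mTOR inhibitor Ddit4 ranged from 6.26 to 18.8 FPKM in expert and up to 8.21 FPKM in naive, where it was listed at 0 in 1 of 6 libraries. Without expert 3 the median log2 fold change of immediate early genes, expert against naive, was 0.21, and the median log2 fold change of glucocorticoid responsive genes, expert against naive, was 0.07, no longer called, and 0.05 without naive 3 and 0.23 without expert 4. With an estimated correlation and all libraries neither list was called (adjusted p = 0.53 for both). The lactate and ketone transporter Slc16a1 stood at 0.68, the taurine transporter Slc6a6 at 0.58 and the proteoglycan Srgn at 0.92. The astrocyte genes Slc1a2, Slc1a3, Gfap, Aqp4, Aldh1l1 and Gja1 stood at 0.21, 0.19, 0.10, 0.17, 0.19 and 0.30, less than their standard errors of 0.29 to 0.50.

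The gene with the smallest p in expert against naive was Pdzk1, a scaffold protein of membrane transporters, at 2.93 ± 0.610 FPKM in expert and 6.02 ± 1.36 in naive (-0.82, SE 0.18). Ctbs, a lysosomal chitobiase, stood at 0.77 (SE 0.22). Dynlrb2 ranged from 4.5 to 16.5 FPKM in expert and, with 4 of 6 naive libraries at 0, passed limma's test when adjusted over the ependymal list alone (adjusted p = 0.0030). The read-through loci Tnfsf12Tnfsf13 and Zfp91Cntf stood at 1.65 and 1.53. They share their sequence with neighbouring genes and were listed at 0 in 2 and 1 of 6 naive libraries. Of the lower genes, Olfr706, Olfr61 and Olfr531 are olfactory receptors of the kind used to measure the background, and were listed at 0 in 4, 5 and 3 of 6 expert libraries. Sval3 was listed at 0 in 3. These 9 genes did not pass, and neither did Sik1 (adjusted p = 1.0 for each). With limma, 0 of 21745 genes were called, and 622 had an unadjusted p under 0.05, of which 312 were higher and 310 lower, against 1087.25 expected by chance. The count ran from 407 (without expert 6) to 965 (without expert 4) when 1 library was left out.

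Camera with the preset correlation called 12 lists for expert against naive, all higher. The adjusted p was 7.980e-14 for endothelial markers and 0.53 with an estimated correlation, 0.53 as well for immediate early genes and for glucocorticoid responsive genes, and fry called 0 lists (smallest adjusted p = 0.79, either direction 0.79). The mean of the endothelial markers differed by 0.54 between the groups (exact permutation p = 0.048, adjusted over 9 marker lists 0.21). The pericyte, smooth muscle and fibroblast list (median 0.26, 12 of 15 higher) and the precursors of oligodendrocytes (median 0.21, 9 of 11 higher) were called too (adjusted p = 0.57 with an estimated correlation for both). Without expert 3 neither was called, with medians of 0.24 and 0.09. The median log2 fold change of pericyte, smooth muscle and fibroblast markers, expert against naive, was 0.16 without naive 4, and the median log2 fold change of oligodendrocyte precursor markers, expert against naive, was 0.11, 0.39 and 0.06 without naive 1, expert 5 and expert 6. With the background covariate the medians were 0.52 for endothelial markers, 0.26 for immediate early genes and 0.29 for pericytes, which stayed called (adjusted p = 0.54, 0.58 and 0.57 with an estimated correlation), and 0.06 for glucocorticoid responsive genes and 0.17 for oligodendrocyte precursors, which did not. The same fit called 3 lists lower, neuron markers (median -0.42), ribosomal proteins (-0.38) and nuclear genes of oxidative phosphorylation (-0.25), at adjusted p = 0.64, 0.54 and 0.54 with an estimated correlation. Expert 3 had the lowest background, at 0.109 FPKM with the next library at 0.681. The covariate fit was not run without it, so whether these 3 calls rest on that library is not known. Without the covariate 18 of 20 neuron markers were lower (median -0.22) and 63 of 70 ribosomal proteins (median -0.16), not called (adjusted p = 0.077 for both), and the median of oxidative phosphorylation was 0.00. Single libraries decided these calls. Without naive 5, naive 6 and expert 2 the median log2 fold change of neuron markers, expert against naive, was -0.40, -0.41 and -0.37, and the list was called, while it was -0.09 without expert 4. Ribosomal proteins were called without naive 5, naive 6, expert 1, expert 2, expert 3 or expert 6, where the median log2 fold change of ribosomal proteins, expert against naive, was -0.32, -0.35, -0.19, -0.29, -0.18 and -0.20, and it was 0.03 without expert 4. Oxidative phosphorylation was called higher without naive 2, naive 4 or expert 4 and lower without naive 6, where the median log2 fold change of oxidative phosphorylation, nuclear genes, expert against naive, was 0.15, 0.14, 0.20 and -0.22.

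Single libraries mattered in expert against naive. Expert 3 was the library of lowest background. Without it 3 lists were called, and without expert 4 it was 21. For astrocyte identity (21 of 22 higher, adjusted p = 0.71 with an estimated correlation), the median log2 fold change of astrocyte identity, expert against naive, was 0.19, and the call was lost without naive 5 (0.05), naive 6 (0.01), expert 2 (0.14) or expert 3 (-0.04). The median was 0.34, 0.30, 0.34 and 0.32 without naive 2, naive 4, expert 4 and expert 5. The call was lost also with the background covariate (-0.06).

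Expert against novice asks what changes between early and full training. Astrocyte genes stood higher in expert libraries than in novice. Gfap was 20.2 ± 8.37 FPKM in expert and 10.6 ± 2.07 in novice (0.81, SE 0.29, n = 6 each). Slc1a2, Slc1a3, Aqp4, Aldh1l1 and Gja1 stood at 0.82, 0.77, 0.72, 0.50 and 0.76. Sox9 was 65.6 ± 26.3 against 33.7 ± 9.27 FPKM (0.90, SE 0.29), and Sqle 18.5 ± 10.1 against 8.33 ± 2.86 FPKM (0.98, SE 0.29). None of these passed (adjusted p = 0.45 to 0.47).

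The genes with the smallest p in this comparison were led by Fkbp9, a peptidyl-prolyl isomerase of the endoplasmic reticulum, at 15.7 ± 3.55 FPKM in expert and 7.99 ± 0.572 in novice (0.87, SE 0.18). The lowest expert value of Fkbp9 was 10.2 FPKM and the highest novice value 8.85 FPKM. Tcf3, a basic helix-loop-helix transcription factor, stood at 0.99 (SE 0.21), the nuclear envelope gene Lemd2 at 1.09, Tulp3, a cilium trafficking gene, at 0.91, and the aminopeptidase Npepl1 at 1.08. Lower in expert stood Elovl3, a fatty acid elongase, at 1.35 ± 0.413 against 5.31 ± 2.58 FPKM (-1.30, SE 0.31), and Il1rapl2 at -1.17. Olfr714, Olfr531 and Accsl were listed at 0 in 4, 3 and 2 of 6 expert libraries. These 10 genes did not pass (adjusted p = 0.45 for each). With limma, 0 of 21745 genes were called, and 2360 had an unadjusted p under 0.05, of which 1061 were higher and 1299 lower, against 1087.25 expected by chance. Leaving out 1 library moved this count from 972 (without expert 3) to 4376 (without expert 4). With age as covariate it was 1389 (smallest adjusted p = 0.67 by limma). Expert mice were 13 to 15 weeks old and novice mice 11 to 13, so age and the stage of training cannot be told apart.

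As groups, several lists of astrocyte function lay above the other genes in expert by camera with a preset correlation, and none was called with an estimated correlation (smallest adjusted p = 0.25). The median over all genes past a filter of 20 FPKM was 0.22 in this comparison. Astrocyte identity had 22 of 22 members higher (median 0.76), with the serine transporter Slc7a10 at 0.83 and the acyl-CoA synthetase Acsbg1 at 0.95. Potassium, water and ion homeostasis had 17 of 17 higher (median 0.66), and the glutamate and GABA lists had medians of 0.36 and 0.51. Metabolic lists were higher as well, with 25 of 29 genes of glycolysis, glycogen and lactate (median 0.46), among them Slc16a1 at 0.77 and the glycogen synthase Gys1 at 0.82, 22 of 24 of cholesterol synthesis (median 0.54) and 20 of 24 of fatty acid metabolism (median 0.53). In the cholesterol list Sqle and Fdft1, at 0.97, passed when adjusted over the list alone. Phagocytosis and complement genes had a median of 0.54, synaptic adhesion genes 0.43 and circadian clock genes 0.29. All 15 endothelial markers stood higher (median 0.54), with Kdr at 0.88 and Pltp at 0.91, and 4 passed when adjusted over the list alone. Of the 37 immediate early genes 21 stood higher (median 0.28), with Jun at 0.71 and Egr4 at -0.99. Hist1h1e stood at 1.02 and passed within its list of histones (8 of 11 higher, median 0.28). Without expert 3 the median log2 fold change of glutamate uptake and metabolism, expert against novice, was 0.19, the median log2 fold change of fatty acid metabolism, expert against novice, 0.33, and the median log2 fold change of immediate early genes, expert against novice, 0.16, and 0.18 without novice 3. The median log2 fold change of replication dependent histones, expert against novice, was 0.45, 0.17 and 0.51 without novice 3, novice 5 and expert 4.

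Camera with the preset correlation called 20 lists for expert against novice, all higher. With an estimated correlation it called 0, at adjusted p = 0.25 for astrocyte identity, potassium, water and ion homeostasis, glycolysis, cholesterol synthesis, phagocytosis, synaptic adhesion, circadian clock genes, endothelial markers and histones, 0.26 for GABA, 0.29 for glutamate and fatty acids and 0.31 for immediate early genes. Fry called 0 (smallest adjusted p = 0.16, either direction 0.17). The mean of the astrocyte identity genes differed by 0.73 (exact permutation p = 0.048, adjusted over 9 marker lists 0.36). With the background covariate 7 of the 20 calls were kept, and 0 with an estimated correlation in the same fit (smallest adjusted p = 0.36). The median of astrocyte identity became 0.20 and that of cholesterol synthesis 0.23, while that of endothelial markers was 0.54. The calls of glutamate (0.08, adjusted p = 0.20), GABA (0.12, 0.14), fatty acids (0.12, 0.079), synaptic adhesion (0.05, 0.050), circadian clock genes (0.11, 0.10), immediate early genes (0.24, 0.079) and histones (0.22, 0.28) were lost. In the same fit oxidative phosphorylation turned from a median of 0.30 (0.18 without expert 3, 0.49 without expert 4) to -0.17 and was called lower, as were neuron markers (-0.61) and ribosomal proteins (-0.38), each at adjusted p = 0.36 with an estimated correlation. The covariate fit was not run without expert 3, the library of lowest background, so whether these calls rest on that library is not known. Neuron markers without the covariate had a median of -0.10, which turned to 0.04 with trimmed mean of M values factors, and were not called (adjusted p = 0.51), except without expert 2, where the median log2 fold change of neuron markers, expert against novice, was -0.28.

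**Figure D3:**
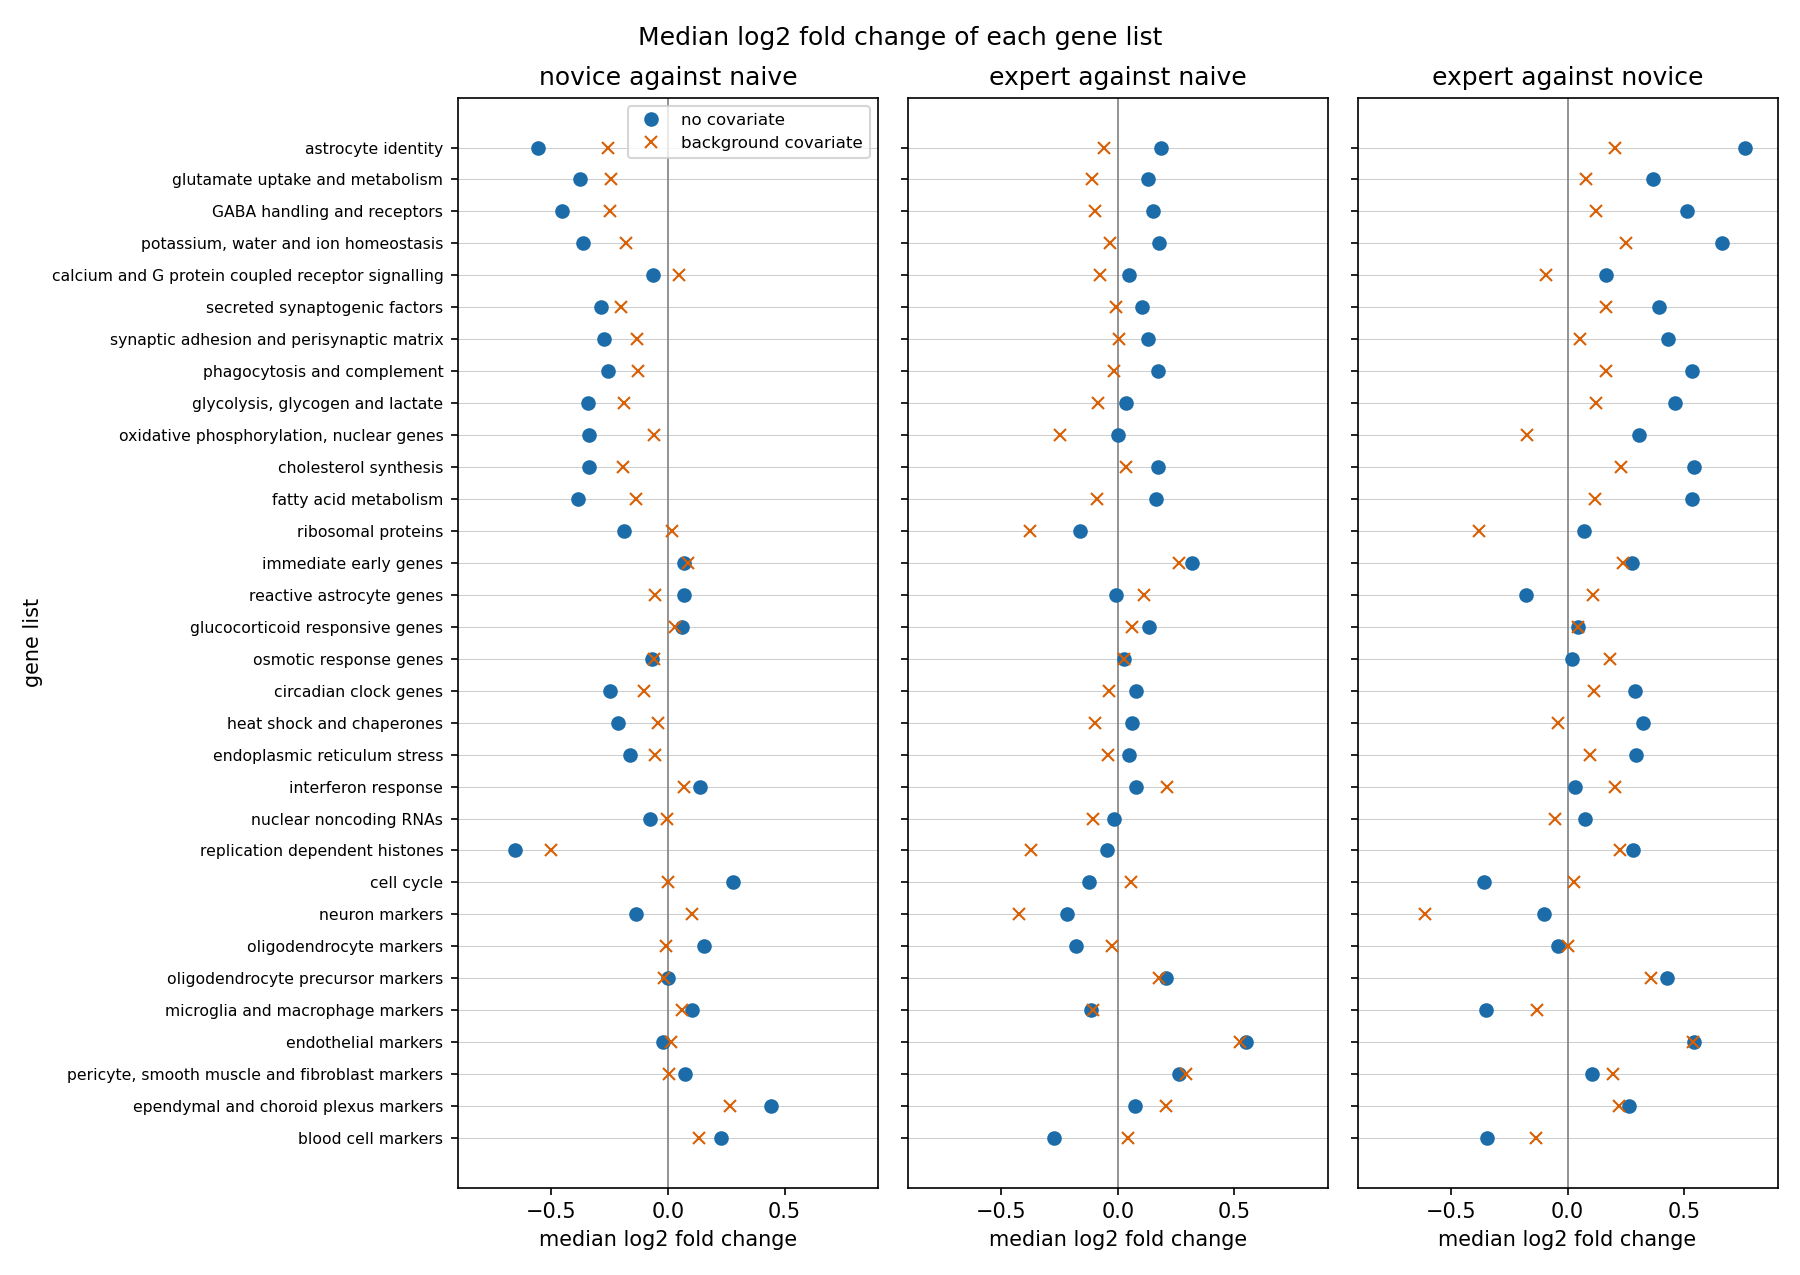
Median log2 fold change of each of 32 gene lists in the 3 comparisons, without a covariate (circles) and with the background as covariate (crosses). Astrocyte identity goes from -0.56 to -0.26 in novice against naive and from 0.76 to 0.20 in expert against novice, while endothelial markers stay at 0.55 and 0.52 in expert against naive.

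Across all 3 groups, the moderated F test of limma called 0 genes, with 1203 at an unadjusted p under 0.05 and a smallest adjusted p of 0.754. The responses of novice and expert, each against naive, were compared across the 21745 genes, which are not independent replicates. Their log2 fold changes had r = 0.23 and a covariance of 0.0387. Both share the naive libraries, and simulated data without any change gave a mean r of 0.47 and a mean covariance of 0.0887, with 89 of 100 simulations at or above the observed r. When the naive libraries were divided into 3 and 3, so that no library was shared, r averaged -0.19 over 20 divisions, from -0.53 to 0.00. No simulation was run for the divided libraries, so this average has no reference value. The signs of the 2 responses agreed for 47.0% of genes, against 64.8% in the simulations. The mean background over silent genes was 2.19 FPKM in novice, 1.75 in naive and 1.38 in expert, and it was not a covariate here. Responses that go apart with training and this difference in background therefore cannot be told apart.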

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

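The tests of explanations and the regroupings of the libraries given here were chosen after the results were seen.

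Signal over silent genes ran from 0.109 to 3.16 FPKM among libraries, and the sexes separate a DNA from an RNA source, since males hold 1 X chromosome while an RNA source has 1 active X in both sexes. Over 72 X-linked silent genes relative to the autosomal ones, the male to female ratio was 0.62 by labelled sex, with male libraries at 0.593 ± 0.0776 (n = 11) and female ones at 0.963 ± 0.138 (n = 4; exact permutation p = 7.326e-04, the smallest that 1365 splits can give), and an earlier estimate over 98 genes gave 0.36. The value of 0.62 argues against RNA transcribed from these genes, and genomic DNA in the libraries, whose amount may differ between preparations, could give it. The earlier estimate lies under the 0.5 that DNA predicts and was replaced after its ratio had been seen. The bound for this test, also set after the results, asked for a low ratio in both estimates. The value of 0.62 thus comes from an estimate chosen with the data in view, and the earlier one adds no separate evidence for either source. Expert 3, novice 1 and novice 3 were left out after their values had been seen. With all 18 libraries as labelled the ratios were 0.58 (permutation p = 0.0057) and 0.43 (0.014), without expert 3 alone they were 0.72 (0.018) and 0.52 (0.057), or 0.59 and 0.32 with sex read from Xist and Ddx3y, and no biological explanation was tested.

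Lower astrocyte identity genes in novice than in naive are the pattern closest to the question of the series. Their mean differed by -0.53 (SE 0.353; exact permutation p = 0.14, adjusted 0.88 over 9 marker lists), 13 of 100 splits gave as large a median, and with the background as covariate the mean differed by -0.27 (SE 0.0893). The exact permutation p of the deviations from the background trend was 0.026, and 0.17 when adjusted over 32 lists, so that a response to training and the background as the whole cause cannot be told apart, because the remaining difference does not pass once all lists are counted. Novice mice were 11 to 13 weeks old and naive mice 12 to 15, apart from naive 2 at 21 weeks, so a fit with age leans on that library. With age as covariate 8 lists were called in place of 16, and 560 genes had an unadjusted p under 0.05 by limma in place of 1000. Without naive 2, and with no covariate, 650 genes did. With age as covariate the median log2 fold change of astrocyte identity, novice against naive, was -0.39 in place of -0.56. Training may lower these genes, and age, the share of astrocytes, handling and water restriction stay open as well.

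With the background subtracted, a filter of 10 FPKM and weighted libraries, 1744 of 4799 genes were called for novice against naive (1271 higher, 473 lower). The same fit with equal weights called 0 genes, with 196 at an unadjusted p under 0.05, so the count is consistent with an effect of the weighting of the libraries. Of 100 splits of the same 12 libraries, 36 gave as many genes, the highest of the others 2953, so chance cannot be excluded. In all, 61 of the other splits called genes. This was 1 of 17 fits looked at while exploring, and 12 of those called no gene.

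For genes called, a real count of 0 is reached by 100 of 100 splits whatever the data, so these splits say nothing about chance for the 3 comparisons, the F test and labelled sex. The highest of the other splits called 4 genes for novice against naive, 71 for expert against naive, 3 for expert against novice and 3 for the F test. Genes at an unadjusted p under 0.05 were as many as the real 1000, 622 and 2360 in 29, 38 and 11 of 100 splits, so chance cannot be excluded for these. Nor can it for lists called, where 39 splits gave at least the 16 of novice against naive (highest other 23), 48 the 12 of expert against naive (highest other 23) and 35 the 20 of expert against novice (highest other 25). For labelled sex, 9 of the other splits called genes, and the highest called 3419. Why that split called so many was not tested. A median as large as that of endothelial markers in expert against naive, 0.55, came from 6 of 100 splits.

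A single library stood apart from the other 5 of its group, by a gap of at least 0.63 of the whole range, in 11 of 209 sets of 6 values. Chance gives this in about 1 of 20 sets, here 10.45. Expert 3 had 5430 genes at exactly 0, and the next expert library 3267. Its mean over oligodendrocyte markers was 2.34 in log2(FPKM + 1), with the nearest at 2.86. Its log2(FPKM + 1) of Tulp3 was 4.12, with the nearest at 3.46. Naive 6 had a mean of 1.84 over microglia and macrophage markers, with the nearest at 2.46. On the same scale Sprr2f stood at 1.64 in naive 1 and Fam229a at 1.87 in naive 5, with the other naive libraries at 0. Ascl5 was at 0 in novice 1, with the nearest at 1.89. Leprel4 was at 2.21 in naive 1, with the nearest at 2.92. Pdzk1 was at 2.36 in expert 6, with the nearest at 1.97. Olfr61 was at 1.0 in expert 1, and the other expert libraries at 0. Olfr714 was at 3.91 in novice 5, with the nearest at 2.25.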

How the results depend on the processing

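The settings that use the background, the filters of 10 and 20 FPKM, sex read from Xist and Ddx3y, and the omission of pairs or classes of libraries were chosen after the data had been seen. Besides the fit reported, 39 fits changed a setting (17 chosen before, 22 after) and 18 left out 1 library.

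In 51 of these limma called 0 genes in the 3 comparisons, with the replicate block among them (smallest adjusted p = 0.087, in expert against novice). Calls came from 6. With the background covariate, a filter of 20 FPKM gave 2 in expert against novice. With library weights as well, a filter of 10 FPKM gave 11 and 5 by the F test, and one of 20 FPKM gave 14, 1 in novice against naive and 4 by the F test. With the background subtracted, a filter of 10 FPKM and weights, novice against naive had 1744 (1761 by the earlier estimate), expert against novice 2 (2) and the F test 2 (1). The 8 libraries of higher background alone gave 3, 4 and 5 in the 3 comparisons and 6 by the F test, with few libraries per group. The cause was not tested for these, except the weights. Array weights alone called 0, with 5394 at an unadjusted p under 0.05 in novice against naive.

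Lists called in novice against naive (16) numbered 10 with quantile normalization, 8 with age, 6 with sex and age, 10 with the background covariate at 5 FPKM and 10 with the background subtracted. Expert against naive (12) had 7 with the covariate and 4 with subtraction, and expert against novice (20) 12 with the covariate. An estimated correlation, with or without the covariate, and fry gave 0 in each comparison. Leaving out 1 library gave 12 to 19, 3 (without expert 3) to 21 (without expert 4) and 18 to 23 lists.

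Medians that changed sign did so mainly with the covariate, at 1 FPKM, at 5 FPKM or with an estimated correlation. In novice against naive, ribosomal proteins went from -0.19 to 0.016, and to 0.081 with subtraction. In expert against naive, astrocyte identity went to -0.059, potassium, water and ion homeostasis to -0.032, circadian clock genes to -0.035, oxidative phosphorylation to -0.25 (-0.18 with weights), and synaptic adhesion to a median of 0.0074 with the test turning lower. In expert against novice, calcium and receptor signalling went to -0.092 (-0.11 at 5 FPKM), oxidative phosphorylation to -0.17, ribosomal proteins to -0.38 (-0.29 with subtraction) and heat shock genes to -0.042. Without expert 3 and naive 6, expert against naive had -0.21 for astrocyte identity, -0.14 for potassium, water and ion homeostasis, -0.051 for synaptic adhesion, -0.37 for oxidative phosphorylation, -0.076 for cholesterol synthesis, -0.18 for fatty acid metabolism and -0.061 for circadian clock genes. Leaving out 1 library gave -0.043 (without expert 3) to 0.34 for astrocyte identity, -0.0017 (without expert 3) to 0.19 for circadian clock genes and -0.22 (without naive 6) to 0.20 for oxidative phosphorylation. Hist1h4d, expert against novice, was 2.24, and -0.090 in the 10 libraries of lower background. The cause was not tested. A further 179 of 3648 pairs of list and setting, and 103 of 12040 of named gene and setting, changed sign with neither value past a threshold.

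The sex effect was 5 genes without novice 1 and novice 3, 5 with sex read from Xist and Ddx3y and 7 with the covariate too. All 3 settings were chosen by Xist and Ddx3y and so are no independent test of the genes on the X and Y chromosomes. The 7 included the autosomal Ecm2 and Fxyd2, lower in female by 1.48 and 1.52 (limma, adjusted p = 0.0045 and 0.0048) and not called in the other fits for sex. The shared response averaged r = -0.19 with naive divided and was 0.15 at 5 FPKM. Whether equal replicate numbers pair libraries was not settled. Of 18 such pairs 10 correlated above 0.1, the lowest at -0.36. Their median correlation was 0.15, against -0.06 for different numbers, but only 1 library matched its own number best. The libraries numbered 1 and 2 were all of lower background and those numbered 5 all of higher background. The count-based test was not run, as fragment numbers could not be recovered. Depth limits genes near the value of 1 fragment, 0.594 to 1.89 FPKM on 1 kb outside expert 3. The simulations behind the shared response reassigned the residuals of all 18 libraries, where those of the naive libraries had been foreseen.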

Other observations

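The lists and comparisons given first were chosen before the data were seen, and the fits with the background covariate after.

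Gene groups not described so far include responses to injury and to interferon. Reactive astrocyte genes had medians of 0.07, -0.01 and -0.18 in novice against naive, expert against naive and expert against novice, with signs that turned under quantile normalization to -0.02, 0.06 and 0.04, and camera called none of the 3 (adjusted p = 0.96, 0.47 and 0.63). Within that list Srgn, Tm4sf1, a membrane protein also found in endothelium, and Osmr, the oncostatin M receptor, stood at 0.92, 0.84 and 0.55 in expert against naive, and Gfap at 0.10, and 0 members passed when adjusted over the list alone. Interferon response genes were called higher in expert against naive (median 0.08, 16 of 22 higher, adjusted p = 0.032, and 0.71 with an estimated correlation). The call was lost without naive 1, naive 2, naive 4, expert 3, expert 4 or expert 5, where the median log2 fold change of interferon response, expert against naive, was 0.05, 0.08, 0.04, 0.09, 0.08 and 0.04. It was 0.13, 0.19, 0.18, 0.13 and 0.18 without naive 3, naive 5, naive 6, expert 1 and expert 2. With the background covariate they were called higher in expert against naive (median 0.21, adjusted p = 0.0017, and 0.54 with an estimated correlation) and in expert against novice (0.20, adjusted p = 0.0099, and 0.36).

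Cell cycle genes had medians of 0.28, -0.12 and -0.36 in the 3 comparisons and were not called (adjusted p = 0.16, 0.44 and 0.069). Single libraries changed this, as the list was called without naive 5, naive 6 or novice 1, where the median log2 fold change of cell cycle, novice against naive, was 0.39, 0.43 and 0.38, and without novice 1, novice 2 or expert 4, where the median log2 fold change of cell cycle, expert against novice, was -0.47, -0.45 and -0.50. With the background covariate the medians were 0.00, 0.06 and 0.03, and the list was not called. Microglia and macrophage markers had a median of -0.35 in expert against novice, with the complement gene C1qc at -0.90 (SE 0.39) and the receptor Csf1r at -0.53, and were not called (adjusted p = 0.30). Oligodendrocyte precursor markers had 6 of 11 higher in novice against naive and were not called (adjusted p = 0.42), with Olig2, Olig1, Pcdh15 and C1ql1 at -0.63, -0.60, 0.30 and 0.43, none past the threshold (adjusted p = 0.89 for each). Fgf2, a growth factor on the list of secreted synaptogenic factors, had medians of 4.35, 7.56 and 7.64 FPKM in naive, novice and expert and was listed at 0 in 1 naive library. Growth factor gene Ctgf stood at 0.91 in novice against naive, and Vcan, a matrix proteoglycan, at 0.54 in expert against naive.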
